A study of Mus musculus with 4 samples.

How the data were processed

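Submandibular and parotid salivary glands were dissected from ICR mouse embryos at embryonic day 12, approximately 10 glands of each kind, per the labels' protocols. Dispase II loosened epithelium from mesenchyme. Each tissue was then dissociated in the cold with a bacterial protease, Accutase and Accumax, and captured on the 10x Chromium droplet system. This gave 4 libraries, 1 per group: parotid epithelium, parotid mesenchyme, submandibular epithelium and submandibular mesenchyme. The 4 libraries were pooled for sequencing, per the labels' protocols, so no sequencing batch separates the groups.

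The deposited values are whole-number counts of unique molecular identifiers (UMIs, each marking 1 captured RNA molecule) per gene and cell barcode, not normalized. Per the submitters' processing notes, Cell Ranger 2.1.1 and the mm10 genome were used. Cell annotations were not used here, so classes were named from markers. The files hold 27998 genes, of which 27645 were matched by Ensembl identifier to a GRCm38 (mm10) annotation for coordinates. Of the symbols in the gene lists, 3 had to be matched by identifier and 1 (Muc19) was not in the files. Together the libraries hold 15351 barcodes and 116478686 UMIs.

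Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which removed 142 barcodes from parotid epithelium, 67 from parotid mesenchyme, 129 from submandibular epithelium and 129 from submandibular mesenchyme. Scrublet, run through scanpy 1.11.5, called 9 of the remaining 14884 barcodes doublets (0.0605%). That is far too few to have worked, so doublets were in effect not removed. As an alternative chosen after the data had been seen, the 27, 156, 114 and 188 barcodes with the highest doublet scores were left out of parotid epithelium, parotid mesenchyme, submandibular epithelium and submandibular mesenchyme. Kept barcodes numbered 14875.

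Each library was clustered on its own, on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 0.8 (igraph 0.11.9, anndata 0.12.19, scikit-learn 1.9.0). A cluster was called epithelial-like, mesenchymal-like and so on from 14 marker lists, and needed at least 3 markers each detected in at least 25% of its cells. The list of periderm and stratified ectoderm markers counted toward the epithelial class. A cluster whose leading genes belonged to another class stayed unnamed. So did a cluster with a median mitochondrial share under 1%, outside the erythroid class, a threshold set after the data had been seen. Of 59 clusters, 57 were named and 2 were not. The unnamed ones held 93 parotid and 140 submandibular epithelium barcodes, with median mitochondrial shares of 0.0966% and 0.0856%. The named classes were checked by ranking each named cluster's genes against the pooled cells of all other classes in all libraries. In none did markers of another class outnumber its own among the 10 leading genes of that ranking, so named classes were compared between libraries. The check used the same markers that had named the clusters, so it cannot show that a class is pure. Ranked against the other clusters of its own library, where subtypes part, 6 named clusters had 1 marker of another class and 0 of their own.

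UMIs were summed over the cells of a class within a library and expressed as CPM, counts scaled to the same total for every class. Epithelial-like cells came from the epithelium libraries and mesenchymal-like cells from the mesenchyme libraries. A gene passed the size rule with at least 50 CPM in the higher library and a ratio of at least 2. Minor classes needed 200 CPM and at least 50 cells in both libraries. With 1 library per group no test between groups exists, so no p-value is given. CPM carry exact 95% Poisson intervals, ratios exact conditional binomial intervals and shares Clopper-Pearson intervals, and these cover counting error only, not differences between animals, litters or dissections. Where a class had no UMI of a gene, the ratio was computed against 3 UMIs over that class for rules and rankings. The text then gives the lower limit of the 95% interval of that ratio, as at least so many fold.

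Named genes followed a fixed rule. They were the 10 highest and the 10 lowest ratios past the size rule for epithelium and mesenchyme, and 5 each way for minor classes. Between tissues, the 10 genes each way with the highest smaller ratio of the 2 glands were named, and likewise 5 each way along the bud to duct range. From every gene list up to 4 members with the largest absolute log2 ratio were named. Haemoglobin, mitochondrial and ribosomal protein genes, unnamed gene models and the sex-linked and immediate early lists stayed out of the top genes. So did genes whose CPM was more than 10 times lower than in another class of at least 20 cells of the same library, which were treated as free RNA. Any gene named outside the rule is marked where it appears, and some genes that the rules take are not reported here.

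The 22 gene lists cover signalling pathways, matrix, keratins, patterning genes, stress genes and markers of other cell types. Members had at least 10 CPM in the higher library, and a list needed 3 of them. A list's median log2 ratio was placed among 10000 random lists of the same size matched on expression. The percentile describes these libraries and is not a test. For the bud to duct range, cells were thinned to 3000 UMIs, which left out 13 submandibular and 77 parotid cells, and scored as bud minus duct genes. Each gene was compared between the highest-scoring and the lowest-scoring cells, 1 in 3 at each end, by a score made without it. That left 1197 submandibular and 558 parotid cells at each end, with 627 and 281 cells near a boundary. The gene lists, markers, size rules, naming rule and most alternatives were fixed before the data were examined.

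The statistics were tested on simulated data drawn from the real means and depths. Each gene was drawn on its own with counting error only, without variation between animals, dissections or cells. The simulations therefore check the calculation, not how often real libraries of the same kind would differ. With 100 genes changed 3-fold, all 100 passed the size rule in the right direction in each comparison, among 2818 simulated genes for epithelium, 2988 for mesenchyme, 794 for skeletal muscle-like and 791 for endothelial-like cells. Of 100 genes changed 1.5-fold, 0 passed, except 1 in the endothelial-like comparison. Of unchanged genes, 0 passed. In simulated unchanged tables, 5.56% of 180 epithelium list medians and 6.25% of 160 mesenchyme list medians lay outside the central 95% of random lists. Genes were drawn independently there, whereas members of a real list can vary together, so these rates do not calibrate the real lists.

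The alternatives tried were no barcode filter, a stricter one (1000 genes, 5% mitochondrial), called doublets kept, Leiden resolutions of 0.4 and 1.6, and a class taken from each cell's own marker score. Others were TMM scaling (edgeR 4.0.16 in R 4.3.3, used for scaling factors only), median-of-ratios scaling, the mean of per-cell CPM, and cells without a Top2a, Mki67 or Cdk1 UMI. CPM minimums 5 times lower and 4 times higher, all kept barcodes, unthinned cells, ends of 1 in 10 cells, and list members of at least 50 CPM were also run. Added after the data had been seen were the highest doublet scores left out, unnamed clusters put in their nearest class, cells with or without a Sox10 UMI, and cells with a Y-linked and no Xist UMI. Computation used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.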

Results

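Single-cell RNA profiles were recorded from the epithelium and the mesenchyme of the submandibular and parotid glands of mouse embryos at embryonic day 12. At this stage each gland is an epithelial bud on a stalk that grows into condensed neural crest-derived mesenchyme. The stated purpose was to describe the cell diversity of these embryonic glands, and the design sets gland against gland and tissue against tissue. Each of the 4 groups had 1 library of pooled glands, so there were no replicates, no difference below has a test, and all intervals are 95% counting intervals. The parotid epithelium library held 1996 barcodes and 14004908 UMIs, with a median of 6662.5 UMIs per barcode. The parotid mesenchyme library held 4488 barcodes and 30815632 UMIs (median 5719). The submandibular epithelium library held 3896 barcodes and 39621166 UMIs (median 9373), and the submandibular mesenchyme library 4971 barcodes and 32036980 UMIs (median 5493). Parotid epithelium was thus the shallowest library in total.

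Which cell classes each library held was asked before genes were compared. Epithelial-like cells made up 95.0% (93.9 to 95.9) of kept parotid epithelium barcodes and 95.7% (95.0 to 96.3) of submandibular epithelium barcodes, the rest being an unnamed cluster in each and 0.584% mesenchymal-like cells in the submandibular library. Mesenchymal-like cells made up 88.5% (87.5 to 89.4) of the parotid mesenchyme library and 87.6% of the submandibular one. Skeletal muscle-like cells were a larger share in the parotid mesenchyme library, 5.29% (4.65 to 5.99) against 2.71% (2.27 to 3.20), but with the stricter barcode filter the intervals overlapped, at 5.63% (4.89 to 6.44) against 4.32% (3.47 to 5.30). Neural crest and glial-like cells, the lineage that forms the parasympathetic ganglion, were 3.02% (2.55 to 3.54; 146 cells) of the submandibular and 0.362% (0.207 to 0.587; 16 cells) of the parotid mesenchyme library. Endothelial-like cells were 2.87% (2.42 to 3.38) against 1.43% (1.10 to 1.82).

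Epithelial-like cells were 2.67% of the parotid mesenchyme library, where no cluster of the submandibular mesenchyme library was named so. The 0 of 4842 cells there came from the clustering: at Leiden resolution 1.6, 19 of its mesenchymal-like cells (0.392%, 0.236 to 0.612) formed an epithelial-like cluster of their own. Chondrogenic-like cells were 1.16% (56 cells) of the submandibular mesenchyme library. Erythroid-like cells were 1.56% of the parotid and 2.19% of the submandibular mesenchyme library, and macrophage-like cells 0.204% and 0.454%. The Dispase separation and the dissection can set these shares. When each cell took the class of its own highest marker score, epithelial-like cells were 76.5% of parotid and 54.7% of submandibular epithelium barcodes, and mesenchymal-like cells 61.5% and 44.1% of the mesenchyme libraries. The minor shares moved too, with neural crest and glial-like cells at 1.95% of parotid and 5.33% of submandibular mesenchyme, endothelial-like cells at 2.31% and 7.62%, muscle-like cells at 6.63% and 4.21%, epithelial-like cells in parotid mesenchyme at 1.52% and chondrogenic-like cells in submandibular mesenchyme at 11.1%.

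**Figure D1:**
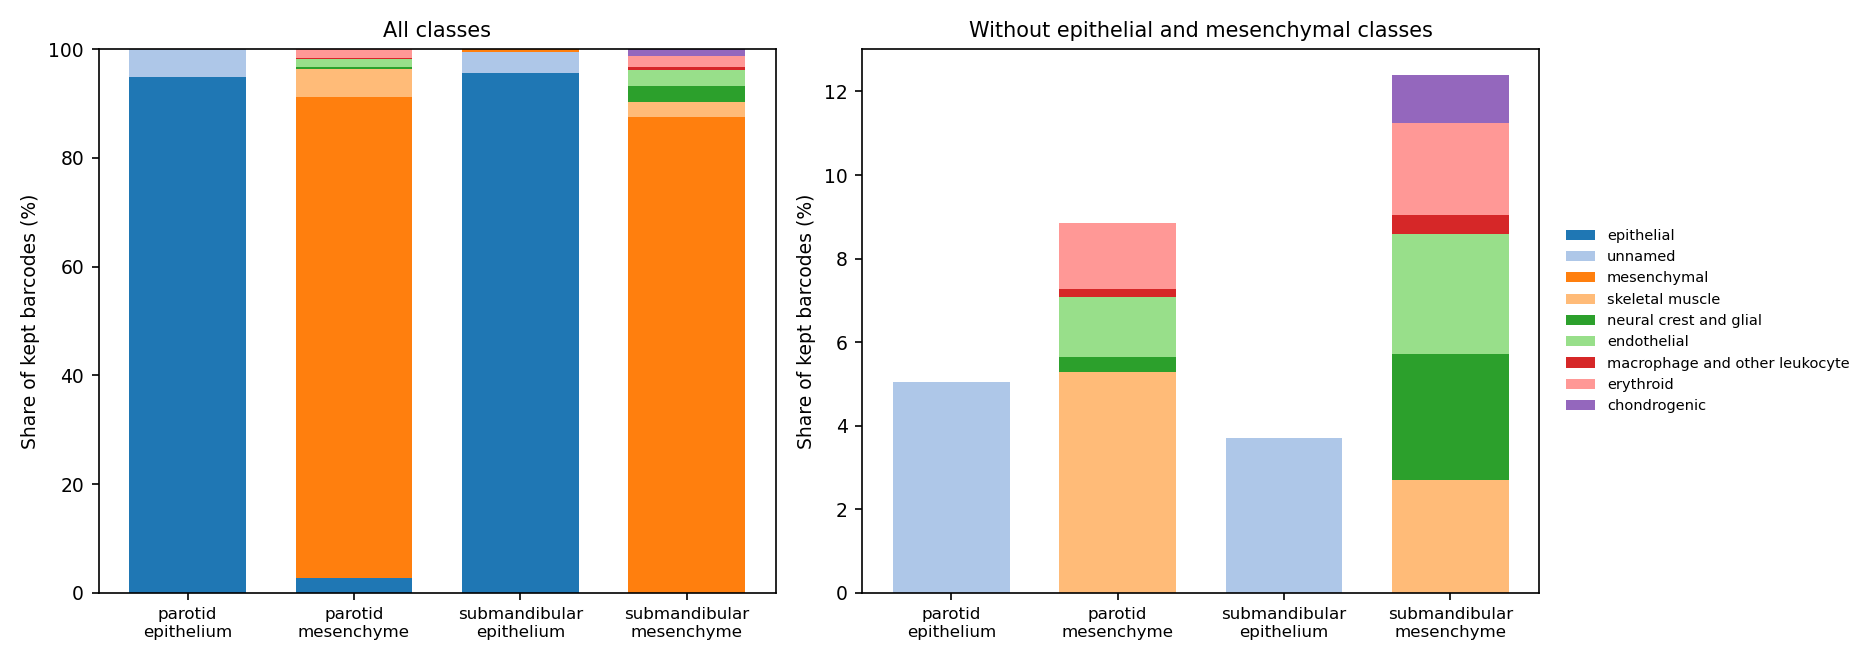
Share of kept barcodes (percent, y axis) in each cell class for the 4 libraries (x axis), for all classes on the left and without the epithelial and mesenchymal classes on the right. Epithelial-like cells fill 95.0% and 95.7% of the epithelium libraries, and skeletal muscle-like cells are 5.29% of parotid and 2.71% of submandibular mesenchyme.

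The comparison of the epithelia asked which genes set the submandibular epithelium apart from the parotid epithelium. Cxcl14, a chemokine (ENSMUSG00000021508, GRCm38 chromosome 13, 56288643 to 56296551, minus strand), was 909.7-fold higher in parotid epithelial-like cells (668 to 1274), at 952 against 1.05 CPM. Krt5, the basal-cell keratin, was also higher there, at 355.5 against 29.5 CPM (12.05-fold, 11.3 to 12.9), and its partner Krt14 at 1037 against 161 CPM. In the submandibular library Dlk1, an imprinted Notch ligand-like gene (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336, plus strand), was 22.1-fold higher (19.2 to 25.6), at 328 against 14.8 CPM.

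Among 3019 genes of at least 50 CPM, 63 were at least 2-fold higher in submandibular and 84 in parotid epithelial-like cells (3605 and 1752 cells). The submandibular side also had Cldn10, a tight-junction claudin (22.4-fold), Hpgd, which degrades prostaglandins (17.5-fold), and Fam150b, a ligand of the receptor kinase ALK (357 against 26.4 CPM, 13.5-fold). Mia (9.87-fold), Tmem59l (6.20-fold), the cartilage-type collagen gene Col9a1 (5.93-fold) and the imprinted noncoding RNA Meg3 (772 against 138 CPM, 5.58-fold) followed. Nutf2-ps1 was 8.79-fold higher, but it is a near copy of Nutf2 and its counts are uncertain. The parotid side was led after Cxcl14 by Gjb6 (39.7-fold) and Gjb2 (278 against 12.8 CPM, 21.7-fold), which encode gap-junction connexins. The glucose transporter gene Slc2a3 (20.8-fold), Lmo1 (15.7-fold), the Iroquois homeobox genes Irx3 (13.7-fold) and Irx5 (10.6-fold), Krt17 (13.2-fold) and Wnt7b (141 against 18.9 CPM, 7.45-fold) came next. The class was 9 clusters in the submandibular and 12 in the parotid library, and ratios over the whole class mix them. In a check chosen after the data had been seen, 10 of the 63 and 13 of the 84 genes were higher in every cluster of their library than in any cluster of the other. Cxcl14 was 1 of these but ranged from 21.5 to 3459 CPM over the parotid clusters, against at most 2.14 CPM in a submandibular one. Irx3 and Irx5 were others, while Gjb6, Gjb2, Slc2a3, Lmo1, Krt17 and Wnt7b were not. With TMM scaling the counts were 69 and 66.

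**Figure D2:**
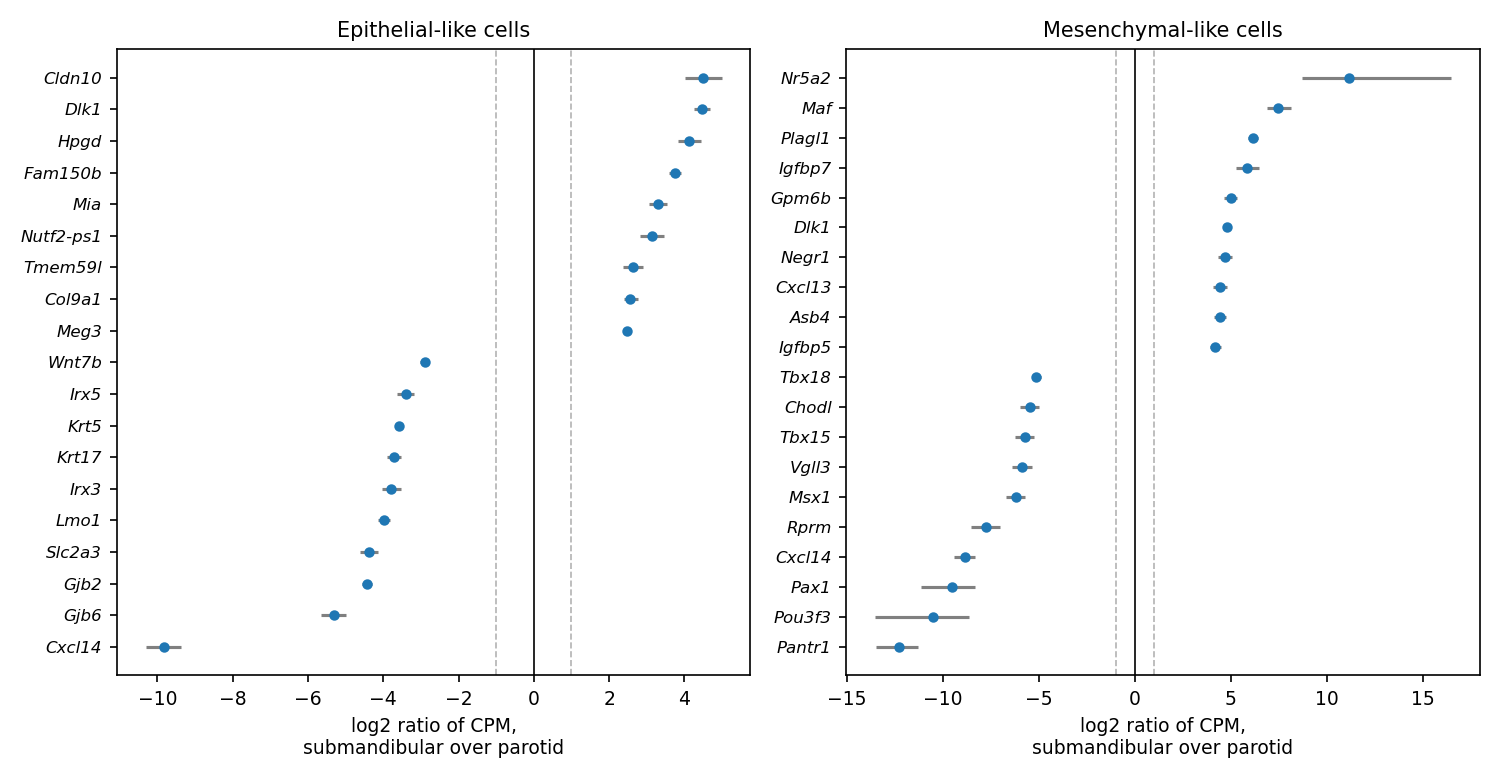
Log2 ratio of CPM, submandibular over parotid (x axis), for the leading genes reported here (y axis) of epithelial-like cells (left) and mesenchymal-like cells (right). Points are the ratios, grey lines their 95% counting intervals, and dashed lines mark a 2-fold ratio. Cxcl14 is far on the parotid side in both tissues, 909.7-fold in epithelium and 464-fold in mesenchyme.

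Keratins as a group were higher in the parotid library, with a median log2 ratio of -1.94 over 8 members, below all 10000 matched random lists. Of these, 5 were at least 2-fold higher in parotid (Krt5, Krt7, Krt14, Krt17 and Krt19), and the simple-epithelial keratins Krt8 (3.37-fold) and Krt18 (2.32-fold) were the 2 higher in submandibular cells. Duct genes, which share keratin members with that list, had a median of -0.68 (percentile 0, 11 members), with Krt7 6.14-fold and Krt19 2.40-fold higher in parotid. Bud genes had a median of 0.70 (percentile 100, 8 members), yet only Etv4, an FGF-induced transcription factor, was 2-fold higher in submandibular cells (111 against 43.6 CPM, 2.54-fold). Fgfr2 (2.54-fold) and Mycn (7.66-fold) were higher in parotid. Sox10, the end-bud transcription factor, was 1.71-fold higher in submandibular cells (1.51 to 1.95). FGF response genes had a median of 0.26 (percentile 98.3, 9 members), with Dusp6 2.04-fold higher. In a check chosen after the data had been seen, among cells with a Sox10 UMI only, the bud median was -0.14, the FGF response median -0.31 and the log2 ratio of Fgfr2 0.15, all 3 of the other sign.

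WNT response genes were higher in the parotid epithelium, with a median of -2.52 over 4 members (percentile 0.05). The WNT effector Lef1 (10.8-fold), the secreted WNT antagonist Dkk4 (45.7-fold, 24.2 to 97.1) and Znrf3 (3.02-fold) were the 3 beyond 2-fold. Hedgehog genes had a median of -2.45 over 5 members (percentile 0), and the 4 at least 2-fold higher in parotid included the receptor gene Ptch1 (5.46-fold) and the coreceptor genes Gas1 (5.48-fold) and Boc (2.47-fold). BMP genes had a median of -0.31 (percentile 2.48, 5 members), with Id1 1.82-fold higher in parotid and Id4 3.33-fold higher in submandibular cells. Notch genes lay within the central 95% of random lists (0.22, 5 members), with the target genes Hey1 3.71-fold higher in submandibular and Nrarp 3.56-fold higher in parotid cells. Retinoic acid genes had a median of 0.71 (percentile 100, 7 members). The receptor gene Rarb (1.76-fold) was higher in submandibular and the binding protein gene Crabp1 (9.24-fold) in parotid cells, and the median was -0.44 among cells with a Sox10 UMI only.

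Patterning genes of the pharyngeal arches, the embryonic segments that form the face and neck, had a median of 1.45 over 10 members (percentile 100). Of these, 8 were at least 2-fold higher in submandibular cells, among them Barx1 (16.5-fold) and Tbx1 (3.87-fold), and 1 was at least 2-fold higher in parotid. In the Sox10 check, chosen after the data had been seen, the arch median among cells with a Sox10 UMI was 0.16 (percentile 90.7, 9 members). There, 2 members were at least 2-fold higher in submandibular and 2 in parotid cells. In cells without a Sox10 UMI the arch median was 1.68 (percentile 100, 11 members). The myogenic list (1.95, percentile 99.9) rested on 3 genes, Tbx1 among them, which are also arch patterning genes. Interstitial matrix genes had a median of -1.10 (percentile 0.03, 6 members), with Dcn, a matrix proteoglycan gene, at 42.3 against 0.209 CPM (202-fold, 102 to 470.4) and Col5a2 9.57-fold higher in parotid. Mesenchymal marker genes below the list's minimum, picked after the data had been seen, went the same way (Lum 5.14 against 0.105 CPM, Col3a1 4.92 against 0.105 CPM), but stayed far lower than Dcn. In parotid epithelial-like cells Dcn had 7.44% (6.82 to 8.10) of its level in parotid mesenchymal-like cells, Lum 0.668% (0.519 to 0.848) and Col3a1 0.593% (0.458 to 0.757), so mesenchymal RNA or cells, which would bring all 3, cannot account for most of the Dcn. Ligands named for mesenchyme had a median of -0.64 (percentile 0, 14 members) and included Wnt6 (449 against 104 CPM, 4.33-fold), the axon guidance gene Sema3a (7.40-fold) and Ntn1 (4.66-fold), all higher in parotid epithelium. Among cells with a Sox10 UMI, the interstitial matrix median was -0.003 (percentile 55.45, 3 members) and the ligand median -0.24 (percentile 10.3, 13 members). In cells without a Sox10 UMI they were -1.06 (percentile 0.01) and -0.47 (percentile 0).

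Epithelial receptor genes (0.09, 12 members), basement membrane genes (-0.11, 8 members), Hox and rhombomere genes (-0.31, 5 members) and proliferation genes (0.18, 14 members) lay within the central 95%. The chemokine receptor gene Cxcr4 was 8.70-fold higher in submandibular cells. The ectodysplasin and neuronal lists had 2 members each and the salivary secretory list 0, too few for a median. In the neuronal list Isl1, a LIM homeobox gene, was 45.1-fold higher in submandibular cells. In all, 14 of the 19 lists with enough members lay outside the central 95% of random lists, against 9 with members of at least 50 CPM and 8 among cells with a Sox10 UMI. Those 8 were the duct, keratin, WNT response, hedgehog, immediate early, FGF response, ectodysplasin and Hox lists. FGF response then lay on the parotid side, and the ectodysplasin and Hox lists were not among the 14. Immediate early and heat shock genes, which respond to dissociation, were higher in the parotid library beside the other lists (median -1.08, 9 of 14 at least 2-fold), with Jun 3.90-fold and Hspa1a 7.26-fold higher. Sex-linked genes also differed (0.42, 3 members), with Xist at 266 against 514 CPM.

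**Figure D3:**
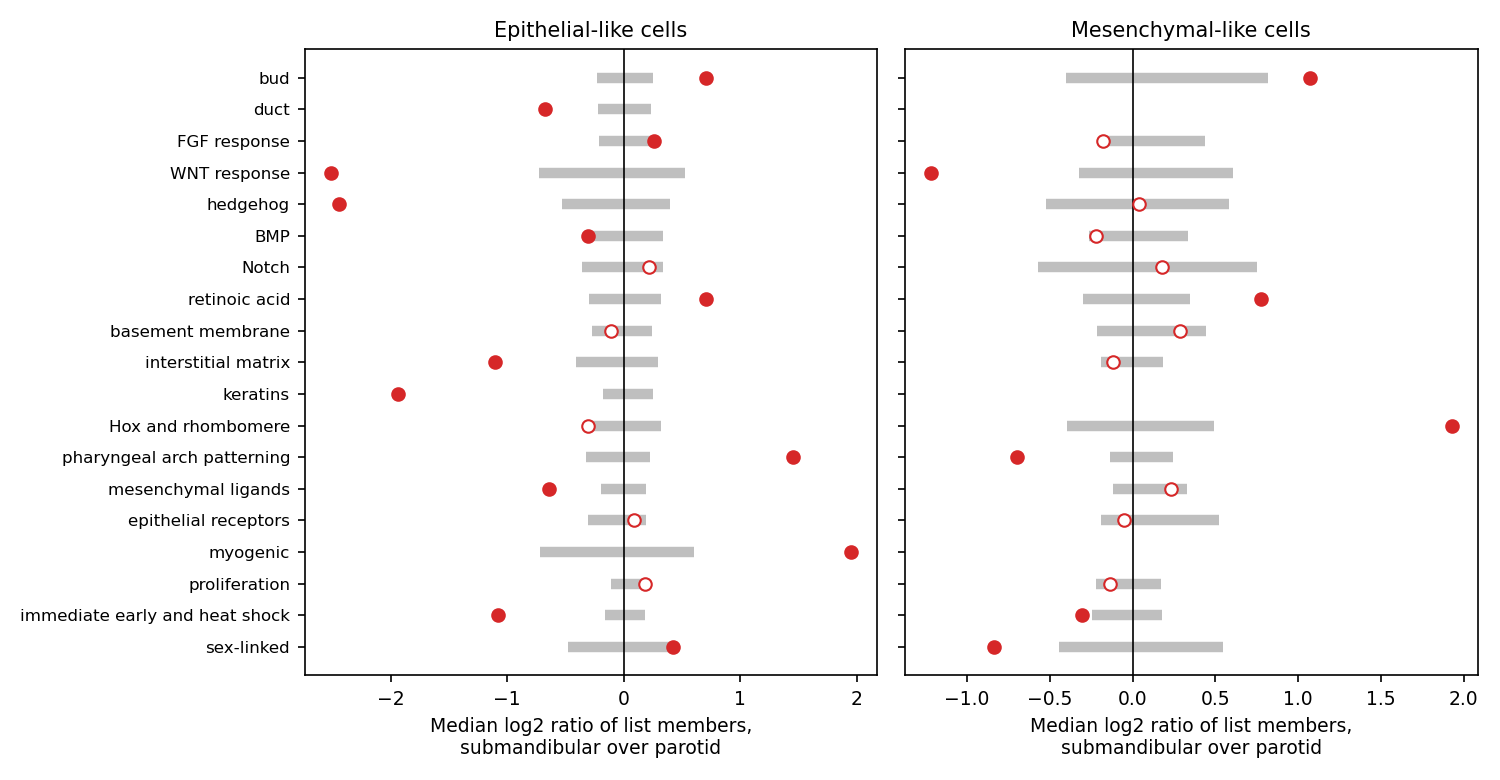
Median log2 ratio of each gene list, submandibular over parotid (x axis), for lists (y axis) with at least 3 members, in epithelial-like (left) and mesenchymal-like cells (right). Grey bars span 2 SD each side of the median of random lists, and filled dots lie outside the central 95% of random lists. WNT response is on the parotid side in both tissues (-2.52 and -1.22), and arch patterning is at 1.45 in epithelium and -0.70 in mesenchyme.

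The same question was asked of the mesenchyme. Nr5a2, an orphan nuclear receptor gene (ENSMUSG00000026398, chromosome 1, 136842571 to 136960448, minus strand), had 2355 UMIs in submandibular and 1 in parotid mesenchymal-like cells, a ratio of 2285 (409.7 to 90278). Maf, a leucine zipper transcription factor gene (177-fold), the imprinted zinc finger gene Plagl1 (339 against 4.81 CPM, 70.4-fold) and Dlk1 (2144 against 78.6 CPM, 27.3-fold) were also higher in submandibular cells. In parotid cells the POU-domain transcription factor gene Pou3f3 (chromosome 1, 42695768 to 42703176, plus strand) had 2809 UMIs against 2, a ratio of 1448 (400.4 to 11960.3). The noncoding RNA Pantr1, which lies next to it on the opposite strand (42590782 to 42694842), stood at 1622 against 0.328 CPM (4951-fold). Cxcl14 was 464-fold higher in parotid mesenchyme (570.4 against 1.23 CPM), the same direction as in epithelium.

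Among 3267 genes of at least 50 CPM, 130 were at least 2-fold higher in submandibular and 118 in parotid mesenchymal-like cells (4242 and 3912 cells). The median of all genes lay 0.11 log2 units above 0, and with TMM scaling the counts were 110 and 144. The class was 9 submandibular and 13 parotid clusters, which these ratios mix. In the cluster check, also chosen after the data had been seen, 55 of the 130 and 40 of the 118 genes were higher in every cluster of their library than in any cluster of the other. Submandibular cells further led in the insulin-like growth factor binding protein genes Igfbp7 (57.0-fold) and Igfbp5 (18.2-fold), the membrane protein genes Gpm6b (31.7-fold) and Negr1 (25.6-fold), the B-cell chemokine gene Cxcl13 (21.6-fold) and Asb4 (21.4-fold). Parotid cells led in several transcription factor genes: the paired-box gene Pax1 (745-fold, 319 to 2297), the homeobox gene Msx1 (99.3 against 1.35 CPM, 73.5-fold) and the T-box genes Tbx15 (53.4-fold) and Tbx18 (238 against 6.80 CPM, 35.1-fold). Rprm (214-fold), Vgll3 (58.3-fold) and Chodl (44.2-fold) were the others. These genes were uneven over the parotid clusters, with Pax1 from 2.60 to 685 CPM and Tbx18 from 11.3 to 1151 CPM, and Msx1, Tbx15, Tbx18 and Vgll3 were not among the 40. On the submandibular side Igfbp7 ranged from 9.93 to 145 CPM over the clusters, and Igfbp5 and Cxcl13 were not among the 55.

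Arch patterning genes went both ways in the mesenchyme: of 26 members, 7 were at least 2-fold higher in submandibular and 11 in parotid cells (median -0.70, percentile 0). The forkhead gene Foxf1 was 236-fold higher (65.0 to 1956) in submandibular cells, against Tbx15 and Tbx18 on the parotid side. In the Hox and rhombomere list no Hox gene was among the named members. The list's median was 1.93 (percentile 99.995, 5 members), and the 4 beyond 2-fold, all higher in submandibular cells, included the cofactor genes Meis1 (4.53-fold) and Meis2 (208 against 54.8 CPM, 3.80-fold). Retinoic acid genes had a median of 0.77 (percentile 99.98, 9 members). The synthesis gene Aldh1a2 (207 against 45.9 CPM, 4.52-fold), the receptor gene Rarb (4.69-fold) and the degrading enzyme gene Cyp26a1 (112-fold, 43.6 to 414) were higher in submandibular cells, and Crabp1 (4.62-fold) in parotid cells. With members of at least 50 CPM only, that median was -0.17.

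WNT response genes were higher in parotid mesenchyme (median -1.22, percentile 0, 5 members), with Lef1 10.1-fold, Axin2 3.01-fold and Nkd1 2.33-fold higher there and the R-spondin receptor gene Lgr5 4.31-fold higher in submandibular cells. The bud list (1.07, percentile 99.4, 5 members) rested in this tissue on the FGF target genes Etv4 (6.07-fold) and Etv5 (2.098-fold) and the laminin gene Lama1 (7.64-fold). FGF response (-0.18), BMP (-0.22), hedgehog (0.04), Notch (0.18), basement membrane (0.29), interstitial matrix (-0.12), mesenchymal ligand (0.23), epithelial receptor (-0.05) and proliferation (-0.13) medians lay within the central 95%. Single members still differed. The growth factor genes Igf1 (472 against 65.4 CPM, 7.22-fold), Fgf7 (10.7-fold) and Bmp7 (8.73-fold) were higher in submandibular cells, Wnt5a (8.67-fold) and Bmp2 (3.65-fold) in parotid cells. Lamb1 (6.14-fold) and Nid2 (5.06-fold) of the basement membrane, the matrix genes Tnc (5.62-fold), Col6a3 (4.54-fold) and Fn1 (3.02-fold), the neurotrophin receptor gene Ntrk2 (7.89-fold) and the Notch target Hes1 (3.18-fold) were higher in submandibular cells.

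The duct, keratin, myogenic and neuronal lists had 2 mesenchymal members each, the ectodysplasin list 1 and the salivary secretory list 0. Of the 16 lists with enough members, 7 lay outside the central 95%. Immediate early and heat shock genes were again on the parotid side (-0.31, percentile 0.55, 3 of 14 at least 2-fold), with Jund 2.15-fold and Hspa1a 8.003-fold higher. Sex-linked genes differed in this pair of libraries (-0.83, percentile 0.17). Xist, the RNA that coats the inactive X chromosome of female cells, stood at 1004 CPM in submandibular and 20.3 CPM in parotid mesenchymal-like cells, and the Y-linked gene Ddx3y was 2.32-fold higher in parotid. Among cells with a Y-linked and no Xist UMI, a check chosen after the data had been seen, 226 of the 248 genes were still at least 2-fold apart in the same direction.

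For the minor classes of the mesenchyme libraries the question was whether gland differences extend to muscle and vessels. The skeletal muscle-like class was 1 cluster of 131 submandibular cells but 2 parotid clusters, of 186 cells and of 48 cells led by Mylpf, Myl1, Acta1 and Tnnc1. Ratios over the whole class therefore mix muscle cell states, which were not compared apart. Acta1, the skeletal actin gene, was 3.68-fold higher in parotid cells (599 against 162 CPM), and the troponin C genes Tnnc1 (2.74-fold) and Tnnc2 (2.71-fold) and the embryonic light chain gene Myl4 (2.44-fold) were higher too. Nutf2 was 2.39-fold higher, but its counts are uncertain because of its near copy. Submandibular muscle-like cells had more Igfbp5 (5.19-fold), Ptn (3.22-fold), the imprinted noncoding RNA Kcnq1ot1 (2.88-fold) and the cell cycle inhibitor gene Cdkn1c (4541 against 1704 CPM, 2.67-fold). Of 822 genes of at least 200 CPM, 10 were at least 2-fold higher in submandibular and 9 in parotid muscle-like cells. These cells were deep, with medians of 12961 and 15487.5 UMIs against 5275 and 5561.5 in mesenchymal-like cells, and all 10 named genes kept their 2-fold ratios with the highest doublet scores left out.

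In endothelial-like cells (139 submandibular, 63 parotid) the counts were 13 and 11 of 830 genes. The arterial connexin gene Gja5 (268 against 90.3 CPM, 2.97-fold), Nfkbia (2.05-fold) and Manf (2.01-fold) were higher in parotid cells. The fatty acid binding protein gene Fabp5 (3.69-fold), the transcription factor gene Tcf15 (3.40-fold) and Itm2a (2.503-fold) were higher in submandibular cells. An entry for the lymphatic chemokine gene Ccl21a had 1823 CPM in submandibular and 0 UMIs in parotid cells, at least 312-fold higher. Several near-identical entries share that symbol, so the value is uncertain. The multi-copy histone gene Hist1h2ap, 10.3-fold higher in submandibular endothelial-like and 6.53-fold in muscle-like cells, is uncertain for the same reason. With the highest doublet scores left out, the parotid count was 5, 21 of the 24 genes kept their direction and 6 of the 8 named genes kept their 2-fold ratios. Haemoglobin RNA was 1.84% of UMIs in parotid and 0.0853% in submandibular endothelial-like cells, so the parotid class held more red-cell RNA. Neural crest and glial-like, neuronal-like and macrophage-like cells were too few in at least 1 library to compare.

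The design also sets epithelium against mesenchyme within each gland, in separate libraries per gland. The transcription factor genes Barx2 (276-fold in submandibular, 366-fold in parotid) and Tfap2a (297-fold and 241-fold) and the ion transport regulator gene Fxyd3 (246-fold and 273-fold) were higher in epithelial-like cells of both glands. Wnt6 was 169-fold and 1772-fold and Krt15 95.0-fold and 2050.1-fold higher in epithelial-like cells of submandibular and parotid. The submandibular values depend on the clustering: 19 cells that leave the mesenchymal-like class at Leiden resolutions 0.4 and 1.6 held 409 of its 424 Krt15 UMIs. Without them Krt15 was 2673-fold, Barx2 1066-fold and Wnt6 at least 683-fold higher in epithelium. The mesenchymal side was led by Mab21l2, with 0 UMIs in submandibular epithelial-like cells (at least 1507-fold) and 1205-fold higher in parotid. The ephrin receptor gene Epha3 (3808-fold, 683 to 150474, and 570.3-fold, 244 to 1757) and the growth factor receptor gene Pdgfra (559-fold and 599-fold) followed.

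The other epithelial genes were Perp, Sfn, Krt14, Cldn4 and Cldn6, from 104-fold (Sfn) to 159-fold (Perp) in submandibular and 205-fold (Perp) to 1446-fold (Krt14) in parotid. Without the 19 cells, the submandibular values were 2634-fold for Sfn, 2062-fold for Perp and at least 1061-fold for Krt14. Among the other mesenchymal genes, Prrx1 had 0 UMIs in submandibular epithelial-like cells (at least 5204-fold, and 358-fold in parotid). The basic helix-loop-helix gene Twist1 was 2235-fold (400.5 to 88343) and 339-fold (116 to 1644) higher. The rest were Col6a1, Fibin, Fez1, Nefl and Runx1t1, from 267-fold (Nefl) to 2720.3-fold (Col6a1) in submandibular and 235-fold (Runx1t1) to 695-fold (Nefl) in parotid. Krt14, Krt15, Perp, Sfn, Cldn6, Pdgfra, Prrx1 and Twist1 had served to name the classes, so their direction follows from the naming. In the submandibular gland, 325 genes of at least 50 CPM were at least 2-fold higher in epithelial-like and 453 in mesenchymal-like cells. In the parotid the counts were 210 and 306. Of the 3036 genes of at least 50 CPM in the comparisons of both glands, 123 were epithelial and 179 mesenchymal in both. The median of all genes lay at -0.27 in the submandibular pair, and TMM scaling gave 526 and 326 genes there and 220 and 295 in the parotid. Across genes, which are not independent replicates, the log2 ratios of the glands correlated with Pearson's r of 0.872 and Spearman's rho of 0.766. The 6 genes at least 2-fold in opposite directions included Cd59a, Cox6b2 and Xist, mesenchymal in submandibular and epithelial in parotid, and Fam150b and Tmem59l, the reverse. Fam150b was 81.4-fold higher in submandibular epithelium than mesenchyme but 2.003-fold higher in parotid mesenchyme than epithelium.

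The last comparison asked whether cells of each epithelium could be ordered from bud to duct, and whether the same genes went with that order in both glands. Etv4 was higher at the bud end in submandibular (3.12-fold) and parotid (14.2-fold), as was Etv5 (2.73-fold and 6.93-fold) and Sox10 (5.08-fold, 3.54 to 7.48, and 18.2-fold, 6.83 to 68.8). Krt19 (12.2-fold and 3.89-fold), Krt5 (13.6-fold and 3.75-fold), Krt7 (6.75-fold and 11.6-fold) and Krt15 (6.45-fold and 2.73-fold) were higher at the duct end. Outside the lists, the neurotrophin receptor gene Ngfr (6.54-fold, and 40.7-fold from 3 duct-end UMIs, 13.6 to 200), the WNT modulator gene Dact2 (3.87-fold and 5.67-fold), Sema6a (3.19-fold and 5.96-fold), Col9a3 (3.11-fold and 11.7-fold) and Fam150b (3.76-fold, and 101-fold from 1 duct-end UMI, 17.7 to 4028) marked the bud end. Upk3bl (10.3-fold and 7.0-fold), the small heat shock protein gene Hspb1 (6.26-fold and 7.18-fold), Ahnak (6.30-fold and 4.74-fold) and the nectin gene Pvrl4 (4.81-fold and 8.06-fold) marked the duct end.

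Bud members were higher at the bud end, with an interval above 1, for 6 of 11 in submandibular and 6 of 10 in parotid. In each gland 2 went the other way: Barx2 and Fgfr2 in submandibular, Fgfr2 and Mycn in parotid. Duct members were higher at the duct end for 10 of 13 in submandibular, with 0 the other way, and 8 of 12 in parotid, with Elf3 the other way. Sox2 was 9.82-fold higher at the submandibular duct end and 1.29-fold (0.604 to 2.79) at the parotid one. Among genes outside the lists, counted in each gland on its own, 48 in submandibular and 41 in parotid were at least 2-fold higher at the bud end. Of these, 11 were so in both glands. At the duct end the counts were 97 and 94, with 35 in both, and 1 gene went opposite ways. Across the 2784 genes outside the lists that were compared in both glands, r was 0.691. With classes by each cell's own marker score the shared bud-end and duct-end counts were 2 and 23. The duct-end count was 10 with the stricter filter, and with 1 in 10 cells at each end the counts were 38 and 91. The ends are ranges of a score, not cell types.

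At a common depth of 3000 UMIs, 8.55% (7.65 to 9.51) of submandibular and 4.90% (3.91 to 6.04) of parotid epithelial-like cells had a Sox10 UMI, against 25.05% and 11.0% at full depth (medians 9838 and 7102 UMIs). Mesenchymal-like cells, which should lack Sox10, had one in 0.0263% of parotid cells and 0 of 4092 submandibular cells (upper bound 0.0901%). A UMI of the cell cycle genes Top2a, Mki67 or Cdk1 was present in 53.3% of submandibular and 39.9% of parotid epithelial-like cells at that depth, and in 28.5% and 28.3% of mesenchymal-like cells. Haemoglobin RNA from red cells, a measure of free RNA, had a UMI in 15.3% of parotid and 5.88% of submandibular epithelial-like cells, and in 97.8% and 98.0% of mesenchymal-like cells.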

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

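The check for opposite directions was chosen after the data had been seen. It covered the 236 named and list genes and took those at least 2-fold higher in the submandibular library of 1 tissue and at least 2-fold higher in the parotid library of the other. With 1 library per group, the difference between tissues was not tested. The 5 genes given here were all higher in submandibular epithelium and in parotid mesenchyme. Fam150b, the ALK ligand gene, had a log2 ratio, submandibular over parotid, of 3.76 in epithelial-like and -3.59 in mesenchymal-like cells, and Tmem59l had 2.63 and -2.36. Hpgd, of prostaglandin breakdown, had 4.13 and -3.82. The homeobox gene Six2 (1.30 and -2.51) and the T-box gene Tbx3 (1.95 and -1.20) are patterning genes. The check asked for 10 CPM in the higher library of each tissue, and some of these values lay under the 50 CPM of the size rule. In mesenchyme Hpgd was at 1.15 (submandibular) against 16.2 CPM (parotid) and Six2 at 2.70 against 15.4 CPM. In epithelium Six2 was at 39.8 against 16.1 CPM and Tbx3 at 17.0 against 4.39 CPM.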

How the results depend on the processing

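Alternatives chosen after the data had been seen were those with the highest doublet scores left out, with unnamed clusters assigned, and by Sox10, Y-linked or Xist UMIs; the others were planned. The main results here are shares and counts, which have no sign to reverse. Of their 365 alternative values, 300 stayed within counting error or within 1.5 times the count and 65 moved. Of 2867 values for single lists and genes, 2215 stayed, 638 moved and 14 reversed. All 147 epithelium genes past the size rule kept their direction in every alternative except cells with a Sox10 UMI, where 141 did. All 248 mesenchyme genes did so except in cells with a Y-linked and no Xist UMI, where 246 did. Of the 147, those still at least 2-fold apart were 96 among cells with a Sox10 UMI, 103 without cycling cells, 115 by own marker score and 121 by the mean of per-cell CPM. The other alternatives kept from 124 to 147. Of the 248, from 216 (all kept barcodes) to 248 stayed at least 2-fold apart. Depth limits the minor classes, with 630948 UMIs in parotid endothelial-like against 13217374 in parotid epithelial-like cells. Endothelial-like cells with the stricter filter or without cycling cells, and muscle-like cells without cycling cells, were too few to run. Where no reason is given, the cause was not tested.

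By each cell's own marker score, which takes a class from few UMIs, epithelial-like shares were 76.5% (parotid) and 54.7% (submandibular), and mesenchymal-like shares 61.5% and 44.1%. In the parotid and submandibular mesenchyme libraries muscle-like shares were then 6.63% and 4.21%, endothelial-like 2.31% and 7.62%, and neural crest and glial-like 1.95% and 5.33%. Epithelial-like cells in parotid mesenchyme were 1.52% and chondrogenic-like cells in submandibular mesenchyme 11.1%. The endothelial-like submandibular count was 22, and the bud-end and duct-end genes shared by both glands numbered 2 and 23. With the stricter filter, shares were 94.1% (submandibular epithelial-like), 91.1% (parotid mesenchymal-like), 4.32% (submandibular muscle-like), 0.764% and 1.93% (parotid and submandibular endothelial-like), 1.73% (epithelial-like in parotid mesenchyme) and 1.84% (submandibular chondrogenic-like), and the shared duct-end count was 10. Without a filter, mesenchymal-like shares were 87.4% (parotid) and 86.1% (submandibular), and endothelial-like shares 1.92% and 3.66%. At Leiden resolution 1.6 the parotid epithelial-like share was 92.9%, and 19 cells of submandibular mesenchyme (0.392%) that had been mesenchymal-like became epithelial-like. At 0.4 the same number left that class and joined the macrophage-like one. With unnamed clusters assigned, epithelial-like shares were 100% and 99.4% by construction. With the highest doublet scores left out, the endothelial-like parotid count was 5, and 6 of the 8 named endothelial genes kept their 2-fold ratios.

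Counts follow the CPM minimum by construction, since it sets how many genes can pass. At 5 times lower and 4 times higher, the submandibular and parotid counts were 215 and 297, then 10 and 24, for epithelium. They were 513 and 330, then 28 and 35, for mesenchyme. For muscle-like cells they were 46 and 41, then 1 and 3, and for endothelial-like cells 76 and 50, then 2 and 6. Between tissues, epithelial and mesenchymal genes of both glands were 401 and 677, then 27 and 45. Those of the submandibular gland were 802 and 1674, then 77 and 91, and those of the parotid 709 and 960, then 44 and 74. Submandibular epithelial genes were 526 with TMM and 511 with median-of-ratios scaling, which recentre the -0.27 shift. With 1 in 10 cells at each end of the score, which lie farther apart, 38 bud-end and 91 duct-end genes were shared. Epithelium lists outside the central 95% were 9 with members of at least 50 CPM, where fewer members remained, and 8 among cells with a Sox10 UMI.

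The reversals were these. Among epithelial cells with a Sox10 UMI, the medians of the bud (-0.14), FGF response (-0.31), retinoic acid (-0.44) and sex-linked (-0.33) lists and the log2 ratios of Ngfr (-0.41) and Fgfr2 (0.15) changed sign. Among cells with a Y-linked and no Xist UMI, chosen on these genes, the sex-linked median was -0.41 in epithelium and 0.31 in mesenchyme, and Eif2s3y was 0.048 in mesenchyme. The mesenchymal retinoic acid median was -0.17 with members of at least 50 CPM. Krt15 in mesenchyme, a keratin at 17.4 against 1.10 CPM, was -0.83 at Leiden resolution 0.4, -0.83 at 1.6, -2.63 by own marker score and -1.49 over all kept barcodes. At both resolutions, the 19 cells that left the class held 409 of its 424 Krt15 UMIs.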

Other observations

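The gene selection in the opening paragraphs, the list of imprinted genes, and all tests of explanations below were chosen after the results had been seen. In the submandibular mesenchyme library, the neural crest and glial-like class (146 cells) carried glial and neurotrophic receptor genes together. Against mesenchymal-like cells of that library, Fabp7, of glial precursors, stood at 288 CPM (46.6-fold), the endothelin receptor gene Ednrb at 220 CPM (336-fold) and the artemin receptor gene Gfra3 at 102 CPM (276-fold). Fabp7 and Ednrb were among the markers that named the class, and Gfra3 was not. Among the 56 chondrogenic-like cells of that library, the cartilage regulators Sox9 (697 CPM, 97.8-fold), Sox5 (119 CPM, 116-fold) and Sox6 (107 CPM, 72.8-fold) were high beside Col2a1 (985 CPM), a marker that named the class.

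Matrix RNA in parotid epithelial-like cells was uneven. Dcn was at 42.3 CPM and detected in 19.1% of cells, while Lum was at 5.14, Col3a1 at 4.92, Col1a2 at 6.43 and Col1a1 at 2.497 CPM. In parotid mesenchymal-like cells the same genes stood at 568 (Dcn), 769.8 (Lum), 829 (Col3a1), 539.7 (Col1a2) and 437 CPM (Col1a1). Submandibular epithelial-like cells had Dcn at 0.209, Lum at 0.105, Col3a1 at 0.105, Col1a2 at 1.20 and Col1a1 at 0.445 CPM, so all 5 genes were higher in the parotid class. The 68 Lum UMIs there lay in 22 cells. As a share of the level in mesenchymal-like cells of the same gland, parotid epithelial-like cells had 7.44% for Dcn, 0.668% for Lum, 0.593% for Col3a1, 1.19% for Col1a2 and 0.571% for Col1a1, so Dcn stood apart from the genes that mesenchymal cells or RNA would bring with it.

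The parotid libraries differed in sex-linked RNA. At full depth a Xist UMI was found in 54.1% of epithelial-like cells of the parotid epithelium library but in 1.48% of mesenchymal-like cells of the parotid mesenchyme library, where 58.0% had a Y-linked UMI. Depth is argued against, since at 3000 UMIs the shares were 49.5% and 1.26%, and so is low Xist in mesenchyme as a tissue, since 55.9% of submandibular mesenchymal-like cells had a Xist UMI at 3000 UMIs. A candidate explanation is that the libraries drew on embryos of different sex mix: among the 118 epithelial-like cells inside the parotid mesenchyme library only 1.69% had a Xist UMI and 55.1% a Y-linked one, as in the mesenchyme around them. Xist UMIs were rare in the other large classes of that library too, in 1.28% of muscle-like, 6.35% of endothelial-like and 2.90% of erythroid-like cells, and 71.4% of muscle-like and 54.0% of endothelial-like cells had a Y-linked UMI. Classes of the submandibular libraries did not always match in this way: a Xist UMI was found in 7.14% (1.98 to 17.3) of 56 chondrogenic-like cells against 57.0% of mesenchymal-like cells of the same library, and in 1 of 22 mesenchymal-like cells of the epithelium library (4.55%, 0.115 to 22.8) against 39.6% of its epithelial-like cells. A single class can thus differ from its library, whereas these classes of the parotid mesenchyme library all had few Xist UMIs. They were not even, since the endothelial-like share (1.76 to 15.5) lay above the 1.48% of mesenchymal-like cells. Xist also reached 113 CPM in the highest mesenchymal-like cluster, against 20.3 CPM over that class. Erythroid-like UMIs were 84.3% haemoglobin, so that class says little about Xist. If the sex mix did differ, the parotid epithelium and mesenchyme libraries did not come from the same set of glands in equal parts.

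Imprinted genes, many of which act in fetal growth, were higher in submandibular mesenchymal-like cells. Of 28 measured, 19 were at least 2-fold higher there and 0 in parotid (median log2 ratio 1.56, percentile 100), among them Plagl1 (70.4-fold), Zim1 (57.1-fold), Dlk1 (27.3-fold), Peg3 (17.6-fold), Cdkn1c (10607 against 1676 CPM, 6.33-fold), Igf2 (2.90-fold) and H19 (2.86-fold). The sex mix is argued against by a median of 1.51 among cells with a Y-linked and no Xist UMI. A few clusters are argued against for 73.7% of the 19 genes (14), which were higher in each of 9 submandibular clusters than in any of 13 parotid clusters. The closest of these was Igf2r, at 31.3 against 31.1 CPM. Of all genes at least 2-fold higher in submandibular cells, 42.3% (55 of 130) lay apart in this way. That set had a higher CPM minimum, held imprinted genes too and was not matched on ratio, so the shares are not directly comparable. An effect on the whole library cannot be told apart from these values: over the 17 imprinted genes measured in both classes, whatever their ratio, the median was 0.50 (quartiles 0.11 to 0.73) in muscle-like and 1.52 (0.45 to 2.66) in mesenchymal-like cells, and the quartiles overlap. Endothelial-like cells had a median of 0.32 over 17 genes, with 4 at least 2-fold higher in submandibular cells and 0 in parotid. In the epithelium libraries the median over 24 genes was -0.10 (quartiles -0.45 to 0.41), with 5 at least 2-fold higher in submandibular, Dlk1 and Meg3 among them, and 2 in parotid. Whether the difference belongs to the gland, or to the embryos and stage sampled, stays open with 1 library each.

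The last pattern was the set of lists that parted the epithelia, weighed against a smaller share of Sox10 cells in the parotid library. Among cells with a Sox10 UMI (903 submandibular, 193 parotid) the keratin median was -0.65 (percentile 0.095) and the WNT response median -2.24 (percentile 0.01), both still on the parotid side, so that share is argued against as their whole cause, though the keratin median lay nearer 0 than the -1.94 of all cells. The bud median, computed without Sox10, was -0.13 (percentile 13.2) in those cells and 0.85 (percentile 100) in cells without a Sox10 UMI. For the bud list the explanation cannot be told apart from a difference within cells, because many Sox10 cells have no Sox10 UMI. A difference between the glands themselves was not tested and may add to each of these lists.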
